A study of Homo sapiens with 12 samples.

How the data were processed

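Gene expression was measured on Affymetrix arrays in A2058 cells, an established human melanoma line, 24 h after the start of treatment. The 12 arrays formed 4 groups of 3: DMSO, the solvent control; dabrafenib (100 nM) with trametinib (10 nM), abbreviated DT; entinostat (1 µM), abbreviated E; and the 3 drugs together at the same doses, abbreviated DTE. Dabrafenib is a RAF kinase inhibitor, trametinib a MEK inhibitor and entinostat an inhibitor of class I histone deacetylases. Groups were taken from the treatment labels. The sample titles call the arrays biological replicates, whereas the series design speaks of technical triplicates, so the p-values measure only the spread between these arrays, which may be technical.

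The authors deposited 1 intensity per probe set and array. The submitters' processing notes name RMA (a background correction, normalization and summary of probe signals) and the Transcriptome Analysis Console, with no versions given. The deposited intensity values were on a linear scale, from about 1.88 to 8728, and the array medians differed, so the values were not left quantile-normalized. Whether a further scaling was applied is not given in the sources used here. Per the labels, an ERCC spike-in mixture was added before RNA extraction. No probe set in the table used here carried an ERCC name (0 probe sets), so the planned centring on the spike-in and the comparison of spike-in levels were not run.

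Of 29396 probe sets, 14748 had a gene symbol, each a single one, and 14648 had none. Symbols were updated through the NCBI gene identifier, which matched for all 14748. Where a gene had several probe sets (156 genes), the one with the highest mean over the 12 arrays was used, which gave 14580 genes. No filter on dim genes was applied. A genome build is not given in the sources used here, so no coordinates are reported. Of the 27 genes named in advance whatever their result, 17 were measured, and the others were not analysed here.

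Intensities were converted to log2, and limma 3.58.1 in R 4.3.3 was used to fit group means over all 12 arrays (lmFit, contrasts and eBayes with default settings, 8 residual degrees of freedom). The comparisons were DT, E and DTE each against DMSO, DTE against DT, DTE against E, and the departure of DTE from the sum of the separate effects on the log2 scale (DTE minus DT, less E minus DMSO). P-values were adjusted by the Benjamini-Hochberg method over all genes within a comparison, and a gene was called changed at an adjusted p under 0.05. The number with at least a 2-fold change is given beside each count. Standard errors are those of the limma fit after moderation, and levels are means ± SD over 3 arrays.

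The comparisons, the tests, the rule for naming genes, 30 gene lists and the processing alternatives were fixed before the data were examined. The lists covered ERK pathway output, homologous recombination, the Fanconi anaemia pathway, non-homologous end joining, base excision and single-strand break repair, mismatch repair, nucleotide excision repair, the DNA damage checkpoint, DNA replication, mitosis, CDK inhibitors, p53 target genes, melanocyte differentiation, dedifferentiated melanoma, receptor tyrosine kinases, the BCL2 family, MHC class I presentation, interferon-stimulated genes, neuronal genes, cancer-testis antigens, histone deacetylases, lysosome and autophagy, cholesterol synthesis, ribosome biogenesis, glycolysis, and epithelial, fibroblast and blood cell markers as signs of other cell types. These 28 lists had measured members, and the remaining lists were not analysed here. Lists were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. List members were counted over all genes and again adjusted over the list alone.

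Named genes were the 6 largest rises and the 6 largest falls against DMSO among called genes whose 3 treated arrays all lay on one side of the 3 DMSO arrays. They were joined by up to 5 each way for DTE against DT and against E, 4 each way for the departure from additivity, up to 2 called members each way per list, and the genes named in advance. The rule yields more genes than are printed. No measure of background per probe set was used here. Means below the lower quartile of genes in a group (2.98 in DMSO, 2.91 in DT, 3.12 in E and 2.99 in DTE) were not shown to lie above background, and the sizes and ranks of changes measured from them are uncertain. Among the genes printed for such a comparison these were CXCL8 in DT, LRP2 in DMSO and DT, RGCC in DT, ETV5 and SPART-AS1 in DTE, SPART-AS1 also in E, NPY6R in E, PMP2 in DMSO, TMEM156 in DMSO, DT and DTE, PRR9 in DT and DTE, DCN in DMSO and DTE, and EPCAM, IFIT1, IFI44L and MGMT in DMSO.

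Because the shift between groups varied with signal level, the counts of changed genes are also given after quantile normalization over all genes (limma) and after centring each array on its median, and most lists also after quantile normalization. The other alternatives were the mean over a gene's probe sets, every probe set tested on its own, keeping only the 9720 brighter genes, trended and robust moderation, array weights, fitting only the groups compared, the replicate number as a block, treat against a 1.2-fold change, and leaving out each array in turn. Alternatives added later were protein-coding genes only, 10000 random gene lists matched on level in 20 bins, the permutation of the residuals of an additive fit over the arrays, and quantile normalization for the overlap and for the effect of one treatment with and without the other.

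No columns were identical (0 columns), and Pearson's r over genes between arrays of a group lay between 0.9898 and 0.9946 over 12 pairs. The fit was tested on simulated data with changes spiked into 200 genes, 5 times over: 1.6% of 1.2-fold changes were recovered, 46.4% of 1.5-fold, 94% of 2-fold and 100% of 3-fold, and 24 of 629 calls were false (3.82%). A simulated list shifted by -0.25 was called in 20 of 20 simulations, against 1 of 540 tests of other lists. The simulated genes varied independently of each other, so these list counts do not give the false-call rate where genes are correlated. With 3 arrays per group, the number of arrays limits the precision, and an exact permutation test of 3 against 3 cannot fall below a p of 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.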

Results

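The series measured gene expression in A2058 melanoma cells given DMSO, dabrafenib and trametinib (DT), entinostat (E) or the 3 drugs together (DTE), with 3 arrays per group. The array medians of the log2 gene values averaged 4.68 ± 0.111 (SD, n = 3) in DMSO, 4.48 ± 0.106 in DT, 4.88 ± 0.0168 in E and 4.66 ± 0.0448 in DTE. The 6 arrays with dabrafenib and trametinib lay 0.21 below the 6 without on the log2 scale (difference -0.21, two-sided exact permutation p = 0.026, or 0.0606 adjusted over the 7 splits tested), and the 6 arrays with entinostat lay 0.19 above the 6 without (exact permutation p = 0.0368, adjusted 0.0644). Permuted only within arrays alike in the other treatment, the exact permutation p was 0.01 for dabrafenib and trametinib and 0.005 for entinostat (adjusted 0.035 for both). Against DMSO alone, the difference was -0.20 for DT (exact permutation p = 0.2), 0.20 for E (p = 0.1, the smallest that 3 against 3 allows) and -0.03 for DTE (p = 0.9). The shift varied with level. With genes in 10 bins by level, the median log2 change in DT against DMSO was -0.02 in the dimmest bin and -0.36 in the brightest. In E against DMSO it was 0.02 in the dimmest bin, reached 0.16 in the middle and was -0.03 in the brightest. Changes are therefore given as deposited and, relative to this shift, after quantile normalization.

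**Figure D1:**
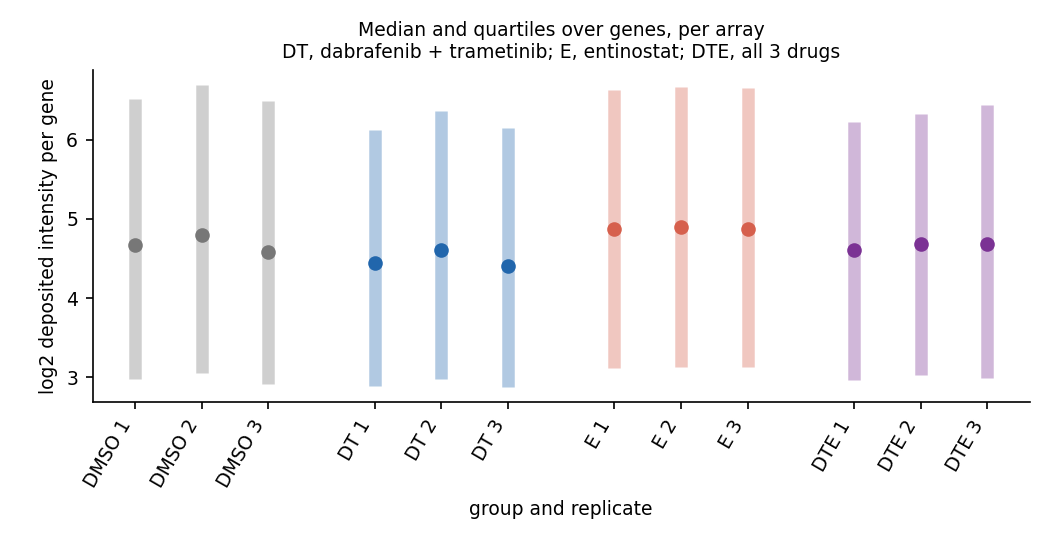
Points show each array's median log2 intensity over genes and bars its quartiles, by group and replicate. The group means of the medians run from 4.48 in DT to 4.88 in E.

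The first comparison, DT against DMSO, asked what inhibition of the MAPK pathway alone did to the transcriptome. The transcriptional output of ERK signalling collapsed. All 17 measured genes of the ERK output list fell, with a median log2 change of -3.24 (-2.92 after quantile normalization, camera adjusted p = 3.73e-33). DUSP6, which encodes a phosphatase of ERK, fell 22.2-fold, from 8.72 ± 0.21 to 4.25 ± 0.20 (SD, n = 3). CEMIP, which encodes a hyaluronan-degrading protein, showed the largest fall among the called genes, 32.9-fold, from 8.78 ± 0.20 to 3.74 ± 0.09. At the same time genes of melanocyte differentiation rose, among them TYRP1, an enzyme of melanin synthesis, 6.4-fold from 6.36 ± 0.10 to 9.03 ± 0.14.

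The next largest falls were in CXCL8, a chemokine (log2 change -4.33, SE 0.13, adjusted p = 7.3e-14), SPRY2, a feedback inhibitor of receptor signalling (-4.24, adjusted p = 2.2e-14), ETV4, an ETS transcription factor (-4.05, adjusted p = 4.2e-13), and FOSL1, an AP-1 subunit (-4.04, adjusted p = 5.6e-14). CXCL8 stood at 2.86 ± 0.15 in DT, below the lower quartile of genes there (2.91), so it was not shown to lie above background, and the size and rank of its fall are uncertain. CCND1, which encodes cyclin D1, fell by 3.35 and MYC by 1.67 (adjusted p = 9.7e-12 and 4.5e-09). With an estimated correlation the ERK output list kept its call (adjusted p = 0.00184). Of the drug targets, MAP2K1, which encodes MEK1, fell by 0.96 (SE 0.12, adjusted p = 8.7e-06; -0.59 after quantile normalization), while MAP2K2 stood at -0.07 (adjusted p = 0.85).

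The largest rises were in ASPA, which encodes aspartoacylase (3.08, SE 0.19, adjusted p = 1.4e-09), CD24, a surface glycoprotein (2.84, adjusted p = 1.3e-10), STK32A, a kinase (2.77, adjusted p = 3.7e-11), TYRP1 (2.68, adjusted p = 1.1e-10), TP53INP2 (2.30, adjusted p = 1.4e-10) and GALNT3, an enzyme of O-glycosylation (2.25, adjusted p = 1.2e-07). CD24 has near-identical pseudogene copies, and which of them its probe set detects was not tested. Of 12 measured melanocyte differentiation genes 6 rose and 0 fell (8 rose when adjusted over the list alone), with a median of 0.65 and, after quantile normalization, 0.98 with 10 rising (camera adjusted p = 1.23e-13; adjusted p = 0.0182 with an estimated correlation). OCA2, a melanosomal transporter, rose by 1.83. MITF, the master transcription factor of the melanocyte lineage, rose by 1.36 (SE 0.15, adjusted p = 2.6e-06), and SOX10 stood at 0.31 (adjusted p = 0.067), or 0.66 (adjusted p = 0.0022) after quantile normalization. In the dedifferentiated melanoma list 9 of 12 genes fell and 0 rose (9 over the list alone; median -0.68, or -0.37 with 6 falling after quantile normalization; camera adjusted p = 0.000192, and adjusted p = 0.405 with an estimated correlation). TNC, an extracellular matrix protein, fell by 1.80, ZEB1, a transcription factor of mesenchymal states, by 1.47, and AXL, a receptor tyrosine kinase, by 0.94.

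Genes of sterol synthesis rose. In the cholesterol synthesis list 8 of 10 rose (9 over the list alone), among them HMGCS1 (1.16) and MVD (0.88), with a median of 0.58 (0.92 after quantile normalization; camera adjusted p = 2.5e-12, and adjusted p = 0.0111 with an estimated correlation). All 11 ribosome biogenesis genes fell, DDX21 by 1.05 and RRP12 by 1.03, with a median of -0.78 (-0.39 with 9 falling after quantile normalization; camera adjusted p = 1.99e-07). The estimated correlation ended that call as deposited (adjusted p = 0.139) but not after quantile normalization (adjusted p = 0.00721).

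Genes of DNA replication, mitosis, homologous recombination and the DNA damage checkpoint lay below DMSO as deposited. In the DNA replication list 14 of 18 fell (16 over the list alone), MCM10 by 0.98 and GINS4 by 0.92; the median of -0.51 became -0.15, with 5 falling, after quantile normalization. In the mitosis list 17 of 22 fell (19 over the list alone), CCNB1 by 0.75 and PLK1 by 0.61; its median of -0.48 became -0.10, with 1 gene rising and 2 falling. In homologous recombination 13 of 19 fell (14 over the list alone), XRCC2 by 0.86 and RAD51AP1 by 0.63 (-0.30 and no longer called after quantile normalization); the median of -0.50 became -0.17, with 1 gene rising and 1 falling. Camera adjusted p-values as deposited were 0.000246, 0.000719 and 0.00552 for replication, mitosis and homologous recombination. They rose to 0.0648, 0.359 and 0.182 after quantile normalization, and the estimated correlation gave an adjusted p of 0.469, 0.572 and 0.572. After median centring homologous recombination kept a median of -0.30, with 1 gene rising and 7 falling (camera adjusted p = 0.00294), and the medians of replication and mitosis were -0.31 and -0.28, with 7 and 5 falling. How far these lists lay below DMSO thus depended on the scale. Among level-matched random lists the medians of replication, mitosis and homologous recombination as deposited lay at percentiles 2.98, 4.64 and 1.4. In the DNA damage checkpoint list 8 of 13 fell (9 over the list alone; median -0.44, or -0.10 with 1 falling after quantile normalization; camera adjusted p = 0.0133, 0.414 after quantile normalization, and adjusted p = 0.572 with an estimated correlation). Its kinase gene CHEK1 fell by 0.97 (-0.58 after quantile normalization).

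The other repair lists passed no list test. In base excision and single-strand break repair 1 of 16 genes rose and 6 fell (adjusted p = 0.328), in the Fanconi anaemia pathway 2 of 4 fell (adjusted p = 0.367), in mismatch repair 2 of 4 (adjusted p = 0.504), in non-homologous end joining 1 of 5 (adjusted p = 0.631), and the 1 measured gene of nucleotide excision repair, RAD23B, fell by 0.47 (list adjusted p = 0.451). The call of RAD23B was lost after median centring (-0.27) and quantile normalization (-0.12). After quantile normalization 1 gene rose and 1 fell in base excision repair, 1 rose in end joining, and 0 were called in the Fanconi and mismatch repair lists. NEIL1, a DNA glycosylase gene, rose by 0.68. PARP1 and XRCC6 stood at -0.38 and -0.36 as deposited and at -0.03 and 0.00 after quantile normalization, and MGMT, at a level of 2.82 ± 0.03 in DMSO, stood at 0.11 (adjusted p = 0.65). In the BCL2 family, the regulators of apoptosis, 2 of 14 genes rose and 6 fell (3 and 3 after quantile normalization; camera adjusted p = 0.571): PMAIP1 and MCL1 fell by 2.69 and 1.51, while BMF and BCL2L11, both promoters of cell death, rose by 1.05 and 0.95. Among 6 p53 target genes 2 rose and 3 fell (2 and 2 after quantile normalization; adjusted p = 0.367), GDF15 by 3.33. The 1 CDK inhibitor measured, CDKN2A, fell by 0.59 (list adjusted p = 0.328).

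In all, 3985 of 14580 genes were called changed, 471 higher and 3514 lower, of which 75 and 390 by at least 2-fold (150 and 187 after quantile normalization), with a median log2 change of -0.17 over all genes. After quantile normalization 2393 genes were called, 1247 higher and 1146 lower, and median centring gave 1178 higher and 1743 lower. Of the genes called as deposited, 470 were also higher and 1146 also lower after quantile normalization, and 0 were called in the opposite direction. The excess of falling genes in this comparison thus depended on the scale. The number of falling genes was 2278 without DMSO replicate 2 and 2267 without DT replicate 1.

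**Figure D2:**
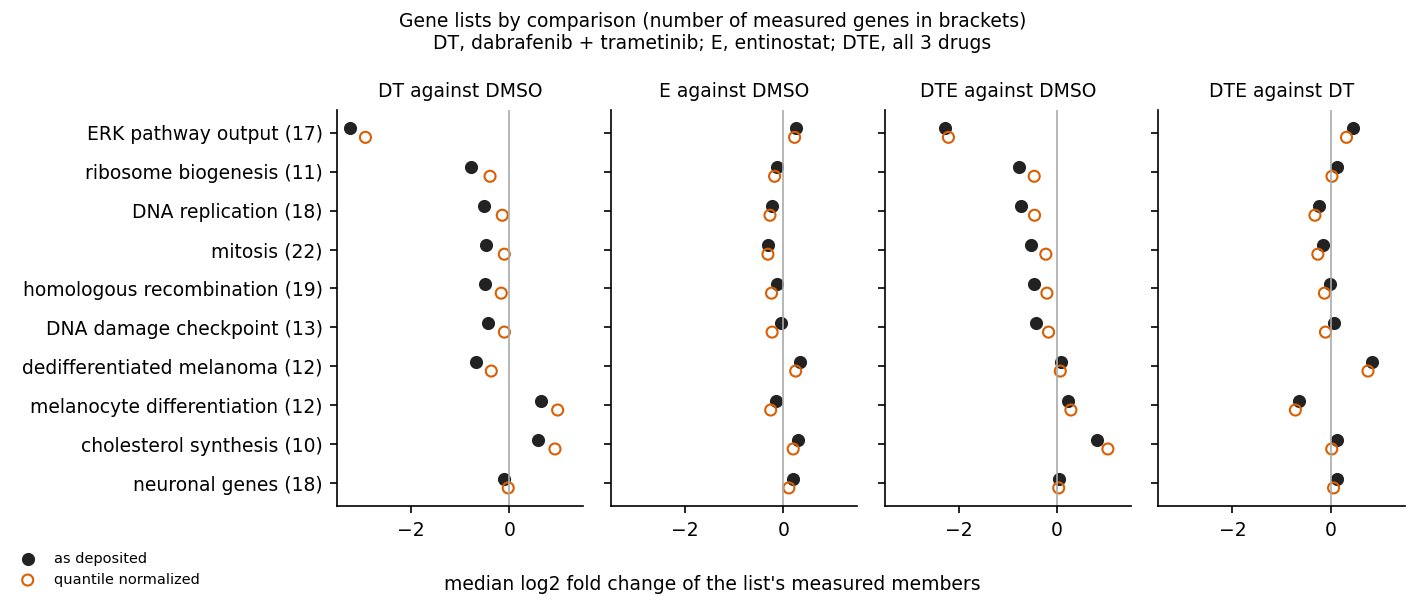
Each point is the median log2 fold change of a gene list's measured members, as deposited (filled) or after quantile normalization (open), in 4 comparisons. The ERK output list fell to -3.24 in DT and -2.29 in DTE, and the melanocyte list rose to 0.65 in DT.

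The comparison of E with DMSO asked what histone deacetylase inhibition did on its own. Most of the genes that moved at least 2-fold rose: 337 against 18 that fell as deposited, 204 against 27 after quantile normalization and 176 against 50 after median centring. IL24, a cytokine gene, rose 14-fold, from 3.93 ± 0.48 to 7.73 ± 0.10 (SD, n = 3), and CD24 rose 10.9-fold, from 3.93 ± 0.25 to 7.39 ± 0.10. The nerve growth factor receptor gene NGFR rose 2.23-fold and MITF fell 1.6-fold. In mitosis 7 of 22 genes fell and in DNA replication 5 of 18, with list medians of -0.30 and -0.23, called by camera at its preset correlation but not with an estimated one (adjusted p = 0.42 for both).

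After IL24 (log2 change 3.80, SE 0.18, adjusted p = 3e-10) and CD24 (3.45, adjusted p = 7.2e-11), the largest rises were in ANKRD1, an ankyrin-repeat cofactor (3.06, adjusted p = 3.7e-10), KIF5C, a kinesin of neurons (3.01, adjusted p = 7.2e-11), BMP6, a secreted growth factor (2.99, adjusted p = 7.9e-08), and KRTAP2-3, a hair keratin-associated protein of a family of close copies (2.85, adjusted p = 6.5e-08). The largest falls were smaller: PRR7-AS1 fell by 1.89 (adjusted p = 3.8e-08) and SPART-AS1 by 1.36 (adjusted p = 1.4e-05), both antisense transcripts, HMGN2, a nucleosome-binding protein with many pseudogene copies, by 1.34 (adjusted p = 1.7e-06), MEPCE, which caps 7SK RNA, by 1.24 (adjusted p = 8.5e-07), RHOJ, a small GTPase, by 1.18 (adjusted p = 1.5e-06), and CA14, a carbonic anhydrase, by 1.16 (adjusted p = 2.2e-05).

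In the mitosis list 7 of 22 genes fell (11 adjusted over the list alone) and 0 rose, KIF20A by 0.74 and CCNB2 by 0.69 (camera adjusted p = 8.43e-10). Its median was -0.31, with 11 falling, after quantile normalization and -0.50, with 20 falling, after median centring. In DNA replication 5 of 18 fell (7 over the list alone), CDC45 by 0.65 and GINS2 by 0.61 (camera adjusted p = 7.36e-07). Its median was -0.27, with 8 falling, after quantile normalization and -0.43, with 15 falling, after median centring. The estimated correlation gave both lists an adjusted p of 0.42 as deposited and of 0.0214 after quantile normalization. In homologous recombination 4 of 19 fell, RAD51AP1 by 0.90 and GEN1 by 0.63, with a median of -0.13 (-0.24 with 6 falling after quantile normalization; camera adjusted p = 0.00409, and adjusted p = 0.529 with an estimated correlation). That median was -0.03 without DMSO replicate 2, -0.07 without E replicate 2 and -0.22 without DMSO replicate 3. CHEK1 fell by 0.85, 1 of 3 falling among 13 checkpoint genes (median -0.04, or -0.23 after quantile normalization; camera adjusted p = 0.0132, and adjusted p = 0.529 with an estimated correlation).

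MITF fell by 0.68 (SE 0.15, adjusted p = 0.004) and TYR, the rate-limiting enzyme of melanin synthesis, by 0.53. In the melanocyte list 1 of 12 genes rose and 3 fell (1 and 4 over the list alone), and the list as a whole just missed the threshold (median -0.15, camera adjusted p = 0.051; -0.26 and 0.0769 after quantile normalization). It passed without DMSO replicate 2 (adjusted p = 0.0396), DT replicate 2 (0.0498), DT replicate 3 (0.0467), E replicate 3 (0.0426), DTE replicate 2 (0.0484) or DTE replicate 3 (0.044). In the dedifferentiated melanoma list 5 of 12 rose and 1 fell (8 and 2 over the list alone). Its median was 0.35 (camera adjusted p = 0.0132, and adjusted p = 0.529 with an estimated correlation). The median was 0.25 after quantile normalization and 0.15, with 3 rising and 2 falling, after median centring. CCN2, a matricellular protein, rose by 1.48 and NGFR by 1.15 (SE 0.13, adjusted p = 5.1e-06). AXL fell by 0.54 (adjusted p = 0.012), a call lost without E replicate 2, where it stood at -0.43.

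Genes of the ERK output list moved little by comparison with DT: 6 of 17 rose and 1 fell (7 and 1 over the list alone), with CXCL8 rising by 1.72 and DUSP5 by 1.49, FOSL1 falling by 0.56, and CCND1 at 0.07 (adjusted p = 0.81). The list's median was 0.26, or 0.23 after quantile normalization and 0.06, with 5 rising and 2 falling, after median centring (camera adjusted p = 0.0481, and adjusted p = 0.529 with an estimated correlation). That call was lost without DMSO replicate 3 (adjusted p = 0.0699), DT replicate 2 (0.0503) or E replicate 1 (0.0932), and the median was 0.11 without DMSO replicate 3 and 0.17 without E replicate 1. In the neuronal list 6 of 18 genes rose and 0 fell (8 over the list alone), SYT11 by 1.58 and MAPT by 1.43, with a median of 0.19 as deposited, 0.11 after quantile normalization and -0.01 after median centring (camera adjusted p = 0.00409, and adjusted p = 0.42 with an estimated correlation). Among 14 receptor tyrosine kinases 7 rose and 2 fell (camera adjusted p = 0.0584, 0.0227 after quantile normalization, 0.0435 without E replicate 2 and 0.0415 without E replicate 3; adjusted p = 0.529 and, after quantile normalization, 0.112 with an estimated correlation): FGFR1 rose by 1.19 and MERTK by 0.95, and ERBB3 fell by 1.07. In cholesterol synthesis 4 of 10 rose (6 over the list alone), STARD4 by 1.48, with a median of 0.31 (camera adjusted p = 0.0169, and adjusted p = 0.42 with an estimated correlation). That median was 0.20 after quantile normalization and 0.11, with 2 rising and 1 falling, after median centring. In ribosome biogenesis 1 of 11 fell (0 over the list alone; median -0.13, or -0.18 after quantile normalization; camera adjusted p = 0.0475, 0.131 after quantile normalization, and adjusted p = 0.529 with an estimated correlation). The ribosome biogenesis call was also lost without DMSO replicate 2 (adjusted p = 0.0658), DMSO replicate 3 (0.0543), E replicate 2 (0.0842) or E replicate 3 (0.0663). The BCL2 family was not called as a list (adjusted p = 0.292).

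Some markers of other cell types rose, although the epithelial and blood cell lists were not called. In the fibroblast list 3 of 5 rose, LUM by 0.93 and THY1 by 0.69 (median 0.45, or 0.38 after quantile normalization; camera adjusted p = 0.0176, and adjusted p = 0.42 with an estimated correlation). Of 9 epithelial markers 3 rose, CLDN4 by 1.07 and EPCAM by 0.73, with a list median of 0.17 as deposited and -0.03 after median centring (adjusted p = 0.128, or 0.0486 without DMSO replicate 1). Of 4 blood cell markers 1 rose, CD68 by 0.63 (adjusted p = 0.436).

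Counted over all genes, 2341 were changed, 1825 higher and 516 lower, and the number lower was 303 without DMSO replicate 2. After quantile normalization 2642 were called, 1410 higher and 1232 lower, and after median centring 1098 higher and 2372 lower, so the balance of rising and falling genes depended on the scale. Of the deposited calls, 1332 were also higher and 514 also lower after quantile normalization, and 0 went the opposite way.

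The question for DTE against DMSO was what the 3 drugs did together. The ERK output genes fell as in DT, all 17 of them, with a median of -2.29 (-2.21 after quantile normalization; camera adjusted p = 7.97e-22, and adjusted p = 0.00798 with an estimated correlation), and all 18 DNA replication genes fell. DUSP6 fell 28.6-fold, from 8.72 ± 0.21 to 3.88 ± 0.48 (SD, n = 3). CD24, raised by each treatment alone, rose 28.9-fold, from 3.93 ± 0.25 to 8.79 ± 0.20. MITF stood between its levels in DT and E, at 7.02 ± 0.23.

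Beside CD24 (log2 change 4.85, SE 0.15, adjusted p = 1.3e-13), the largest rises were in A2M, a protease inhibitor (3.33, adjusted p = 7.3e-12), ANKRD1 (3.18, adjusted p = 5.7e-11), BMP6 (3.10, adjusted p = 2.1e-08), PI15, a peptidase inhibitor (3.10, adjusted p = 2.2e-09), and LRP2, the endocytic receptor megalin (3.00, adjusted p = 1.8e-12). The largest falls were in DUSP6 (-4.84, SE 0.19, adjusted p = 4.1e-12), CEMIP (-4.69), FOSL1 (-4.01), ETV4 (-3.80), ETV5 (-3.58) and SPRY4 (-3.49). CCND1 fell by 2.55 and MYC by 1.23. AXL fell by 1.19 (adjusted p = 5.1e-06). TYRP1 rose by 1.22 and OCA2 by 1.14, and 5 of 12 melanocyte genes rose while 2 fell, among them BCL2A1 by 1.24 (median 0.23, camera adjusted p = 0.0745). That median was 0.12 without DMSO replicate 1 and 0.15 without DTE replicate 3. After quantile normalization the melanocyte list was called (median 0.28, camera adjusted p = 0.0152, and adjusted p = 0.0887 with an estimated correlation), as it was without DTE replicate 2 (adjusted p = 0.0464 as deposited). The dedifferentiated list was mixed, with 3 of 12 rising and 4 falling (camera adjusted p = 0.786; median 0.08 but mean -0.11), CCN2 rising by 1.45 and SOX9 falling by 1.55.

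In DNA replication the median was -0.73 (-0.46 with 14 of 18 falling after quantile normalization; camera adjusted p = 1.31e-08). The estimated correlation gave an adjusted p of 0.196 as deposited and 0.0046 after quantile normalization. CDC45 fell by 1.23 and MCM7, a subunit of the replicative helicase, by 1.14. Of 22 mitosis genes 18 fell (19 over the list alone), PLK1 by 1.00 and AURKA by 0.94 (median -0.52, or -0.23 with 10 falling after quantile normalization; camera adjusted p = 3.84e-06, and adjusted p = 0.482 with an estimated correlation). In homologous recombination 12 of 19 fell and 1 rose (14 and 1 over the list alone), RAD51AP1 falling by 1.00 and PALB2 by 0.94. Its median was -0.46, or -0.21 with 7 falling after quantile normalization (camera adjusted p = 0.00583 and 0.0482; adjusted p = 0.515 with an estimated correlation). In base excision and single-strand break repair 7 of 16 fell (10 over the list alone), UNG by 1.10 and XRCC1 by 0.75 (median -0.32, or -0.10 after quantile normalization; camera adjusted p = 0.0275, 0.204 after quantile normalization, and adjusted p = 0.515 with an estimated correlation). CHEK1 fell by 1.05, 1 of 8 falling among 13 checkpoint genes (9 over the list alone; median -0.43, or -0.17 after quantile normalization; camera adjusted p = 0.00773, 0.0611 after quantile normalization, and adjusted p = 0.515 with an estimated correlation). XRCC6 stood at -0.41 as deposited and -0.11 after quantile normalization, and PARP1 at -0.30 and 0.00.

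In cholesterol synthesis 9 of 10 genes rose, STARD4 2.83-fold and HMGCS1 2.37-fold (median 0.81, or 1.03 after quantile normalization; camera adjusted p = 1.31e-08, and adjusted p = 0.035 with an estimated correlation). All 11 ribosome biogenesis genes fell, with a median of -0.77, or -0.46 with 8 falling after quantile normalization (camera adjusted p = 6.86e-06 as deposited). The estimated correlation gave that list an adjusted p of 0.196 as deposited and 0.0264 after quantile normalization. In the BCL2 family 2 of 14 rose, BMF by 1.17 and BCL2L11 by 1.01, and 9 fell, among them PMAIP1 by 1.34 (median -0.44, or -0.20 with 2 rising and 5 falling after quantile normalization; camera adjusted p = 0.11). Receptor tyrosine kinases went both ways, with 6 of 14 rising, KIT by 1.98, and 3 falling, DDR2 by 0.82 (median 0.14, or 0.30 after quantile normalization; camera adjusted p = 0.0432, 0.0534 without DTE replicate 3, and adjusted p = 0.515 with an estimated correlation). Among the fibroblast markers LUM rose by 1.63 and DCN by 0.67, 2 of 5 (median 0.13, or 0.17 after quantile normalization; camera adjusted p = 0.0266, 0.0611 after quantile normalization, and adjusted p = 0.196 with an estimated correlation).

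This comparison called 4690 genes, 1405 higher and 3285 lower, of which 327 and 280 by at least 2-fold (430 and 149 after quantile normalization), with a median log2 change of -0.11. Quantile normalization gave 4129, 2065 higher and 2064 lower, and median centring 1604 higher and 3361 lower. Of the deposited calls, 1379 were also higher and 2007 also lower after quantile normalization, and 0 went the opposite way.

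**Figure D3:**
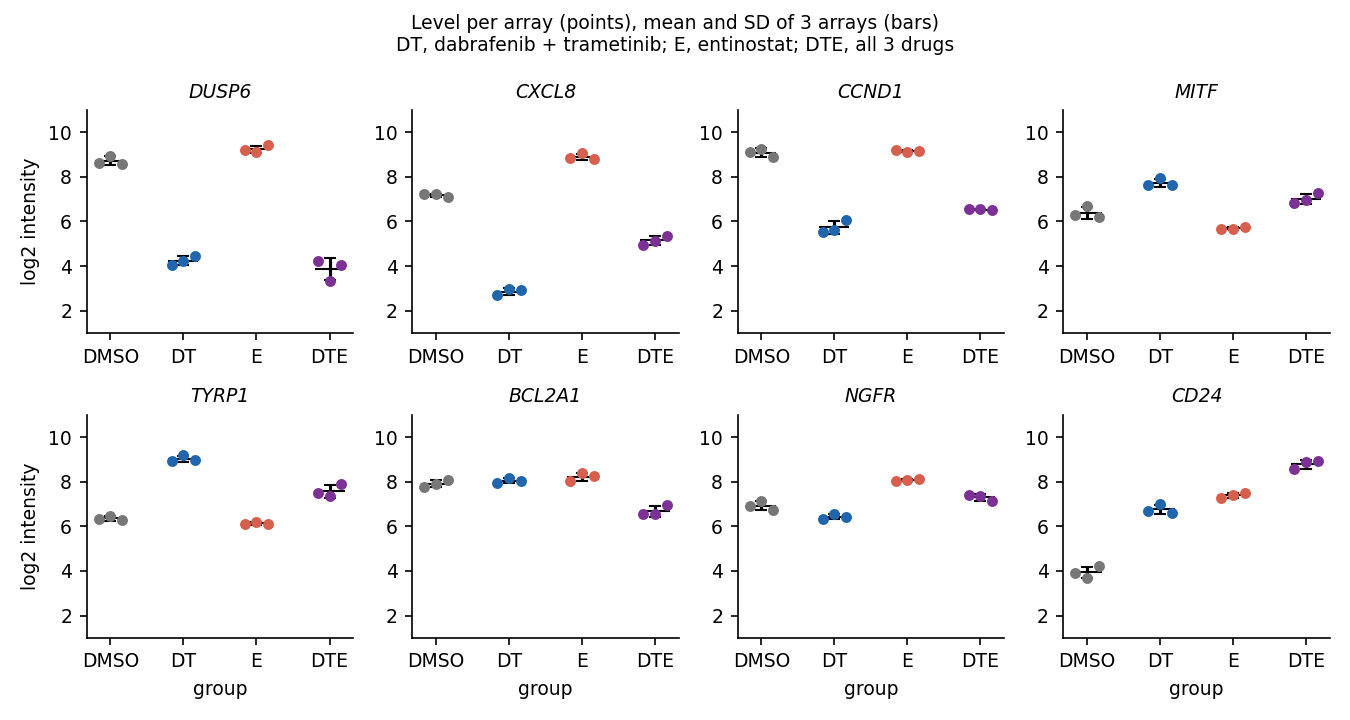
Log2 intensity of 8 genes on each array (points), with the mean and SD of 3 arrays (bars), by group. DUSP6 falls to 4.25 in DT and 3.88 in DTE, TYRP1 reaches 9.03 in DT and 7.58 in DTE, and CD24 is highest in DTE at 8.79.

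DTE against DT asked what entinostat added to MAPK pathway inhibition. Melanocyte genes were lower than in DT when entinostat was present: 10 of 12 in the list fell and 0 rose, with a median of -0.65 (-0.72 with 11 falling after quantile normalization; camera adjusted p = 1.2e-09, and adjusted p = 0.138 with an estimated correlation). TYRP1 fell by 1.46, from 9.03 ± 0.14 to 7.58 ± 0.28 (SD, n = 3), and MITF by 0.71, from 7.73 ± 0.19 to 7.02 ± 0.23 (adjusted p = 0.0021). Genes of the dedifferentiated list rose, 7 of 12, with CCN2 up by 1.87 and ZEB1 by 1.04, and so did 3 of 5 fibroblast markers. Neither list was called with an estimated correlation (adjusted p = 0.508 and 0.279). ERK output genes were partly higher, IER3 by 1.96 and CXCL8, from its low level in DT, by 2.30.

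Over the melanocyte list alone 10 genes fell and 1 rose. After quantile normalization that list was also called with an estimated correlation (adjusted p = 0.00695). The dedifferentiated list had a median of 0.84, or 0.75 after quantile normalization (8 rising and 1 falling over the list alone; camera adjusted p = 0.000325, and adjusted p = 0.508 with an estimated correlation). In it NGFR rose by 0.87 (adjusted p = 8.2e-05). The fibroblast markers list, a sign of another cell type, had a median of 0.53, or 0.38 with 2 of 5 rising after quantile normalization (4 rising over the list alone; camera adjusted p = 0.0209, 0.0228 after quantile normalization, 0.0513 without DTE replicate 1, and adjusted p = 0.279 with an estimated correlation). The median of the fibroblast markers list was 0.34 without DTE replicate 2. Of 17 ERK output genes 9 rose and 0 fell (median 0.44, or 0.32 after quantile normalization; camera adjusted p = 0.000828, and adjusted p = 0.426 with an estimated correlation). CCND1 rose by 0.80 (adjusted p = 5e-04), while DUSP6 stood at -0.36 (adjusted p = 0.22) and SPRY4 at -0.25 (adjusted p = 0.37). IER3 had a second, dimmer probe set, which stood at 0.40.

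The largest rises were in ANKRD1 (3.73, SE 0.15, adjusted p = 2.5e-11), LRP2 (3.16, adjusted p = 4.4e-12), COLEC12, a scavenger receptor (2.98, adjusted p = 2.6e-09), RGCC (2.95, adjusted p = 2.6e-09) and CREB3L3, a transcription factor (2.92, adjusted p = 9.6e-11). The largest falls were in GALNT3 (-2.07, SE 0.19, adjusted p = 5.2e-07), CA14 (-1.93, adjusted p = 5.8e-08), UBAP1L (-1.69, adjusted p = 7e-07), SPART-AS1 (-1.68, adjusted p = 9.3e-07) and EDNRB, the endothelin receptor B of melanocytes (-1.49, adjusted p = 1.7e-07). DNA replication genes were lower, 6 of 18 falling (7, with 1 rising, over the list alone; median -0.24, or -0.32 with 11 falling after quantile normalization; camera adjusted p = 0.000145). The estimated correlation gave an adjusted p of 0.514 as deposited and 0.0337 after quantile normalization. Homologous recombination as a list was not called (1 of 19 rising and 1 falling, adjusted p = 0.633), and UNG, a uracil DNA glycosylase, fell by 0.60. Among receptor tyrosine kinases 8 of 14 rose and 2 fell, ROR1 rising by 1.00 and ERBB3 falling by 1.08 (median 0.42, or 0.29 after quantile normalization; camera adjusted p = 0.0228, 0.0527 without DTE replicate 1, and adjusted p = 0.829 with an estimated correlation). PMAIP1 rose by 1.35 and BCL2A1 fell by 1.36.

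Over all genes 2756 were changed, 2014 higher and 742 lower, of which 399 and 37 by at least 2-fold (301 and 74 after quantile normalization), with a median of 0.06. The number lower was 473 without DT replicate 2. After quantile normalization 3538 were called, 1786 higher and 1752 lower (1745 and 742 of them also called as deposited, 0 in the opposite direction), and after median centring 1364 higher and 2245 lower.

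DTE against E asked what dabrafenib and trametinib added in the presence of entinostat. The ERK output again fell in all 17 genes, with a median of -3.15 (-2.93 after quantile normalization; camera adjusted p = 1.41e-37, and adjusted p = 0.00117 with an estimated correlation). DUSP6 fell 41-fold, from 9.24 ± 0.15 to 3.88 ± 0.48 (SD, n = 3), the largest fall among the called genes of this comparison. MITF rose 2.5-fold, from 5.70 ± 0.05 to 7.02 ± 0.23, and BCL2A1, an anti-apoptotic BCL2 family member, fell by 1.54.

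After DUSP6 (log2 change -5.36, SE 0.19, adjusted p = 8.1e-13), the largest falls were in CEMIP (-4.43, adjusted p = 7.5e-14), ETV4 (-4.05, adjusted p = 6.6e-13), SH2D2A, an adapter protein (-3.97, adjusted p = 4.7e-12), and SPRY4 (-3.77, adjusted p = 2.4e-11). The largest rises included A2M (2.16, SE 0.14, adjusted p = 3.3e-09), PI15 (2.08, adjusted p = 4.8e-07), NPY6R, annotated as a receptor pseudogene (1.89, adjusted p = 3.2e-07), and PMP2, a myelin protein (1.70, adjusted p = 9.5e-07). Of 12 melanocyte genes 6 rose and 2 fell, TYRP1 rising by 1.43 (median 0.27, or 0.58 with 8 rising after quantile normalization; camera adjusted p = 3.82e-06). With an estimated correlation the adjusted p was 0.172 as deposited and 0.007 after quantile normalization. In the BCL2 family 2 of 14 rose and 10 fell (median -0.52, or -0.24 with 4 falling after quantile normalization; camera adjusted p = 0.0235, 0.0679 without DTE replicate 3, and adjusted p = 0.32 with an estimated correlation). Cholesterol synthesis genes rose, 3 of 10 as deposited (4 over the list alone) and 9 after quantile normalization (median 0.29 and 0.61; camera adjusted p = 5.63e-09, and adjusted p = 0.029 with an estimated correlation). DNA replication genes fell, 11 of 18 (15 over the list alone; median -0.45, or -0.15 with 4 falling after quantile normalization; camera adjusted p = 0.000286, and adjusted p = 0.471 with an estimated correlation), CDT1 by 0.94. All 11 ribosome biogenesis genes fell (median -0.56, or -0.27 with 4 falling after quantile normalization; camera adjusted p = 2.93e-05). The estimated correlation gave that list an adjusted p of 0.301 as deposited and 0.0272 after quantile normalization. Homologous recombination was not called (6 of 19 falling, adjusted p = 0.542), and its median of -0.23 became 0.06 after quantile normalization.

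This comparison called 3574 genes, 303 higher and 3271 lower, of which 43 and 255 by at least 2-fold (85 and 128 after quantile normalization), with a median of -0.19. The number lower was 2132 without DTE replicate 1. Quantile normalization called 1870 genes, 1019 higher and 851 lower (298 and 851 of them also called as deposited, 0 in the opposite direction). Median centring called 1985, 978 higher and 1007 lower.

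The test of additivity asked whether DTE differed from the sum of the DT and E effects on the log2 scale. It did for 151 of 14580 genes, 82 above the sum and 69 below (1683 genes at an unadjusted p under 0.05), and 124 of the 151 were changed in DT against DMSO and 82 in E against DMSO. The clearest group below the sum was melanocyte differentiation, with a median departure of -0.50 (-0.55 after quantile normalization; camera adjusted p = 3.2e-07, and adjusted p = 0.293 with an estimated correlation): 3 of 12 genes were called below the sum (7 adjusted over the list alone) and 0 above. BCL2A1 was the furthest below in that list: it stood at 7.92 ± 0.14 in DMSO, 8.04 ± 0.11 in DT, 8.22 ± 0.18 in E and 6.68 ± 0.24 in DTE (SD, n = 3). TYRP1 was 1.24 below the sum (departure -1.24). MITF itself did not depart (-0.03, 95% interval -0.478 to 0.412, adjusted p = 0.98).

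The largest departures above the sum were in SMAGP (1.55, SE 0.20, adjusted p = 0.00061), CTLA4, an inhibitory receptor best known in T cells (1.55, SE 0.17, adjusted p = 0.00028), DKK1, a secreted WNT antagonist (1.54, SE 0.21, adjusted p = 0.00098), and PMP2 (1.53, SE 0.24, adjusted p = 0.0026). DKK1 fell in DT, to 5.74 ± 0.30 from 7.61 ± 0.11, but stood at 8.46 ± 0.19 in E and 8.13 ± 0.05 in DTE. The largest below were in TP53INP2 (-1.74, SE 0.17, adjusted p = 0.00011), BCL2A1 (-1.67, SE 0.20, adjusted p = 0.00049), TMEM156 (-1.62, SE 0.26, adjusted p = 0.0034) and PRR9 (-1.54, SE 0.26, adjusted p = 0.0068). PMAIP1, which promotes apoptosis, lay 1.11 above the sum, and among ERK output genes IER3 lay 1.29 and EPHA4, an ephrin receptor, 1.25 above. The call of IER3 was lost with the mean of its probe sets, of which the dimmer one stood at -0.14.

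After quantile normalization the melanocyte list was also called with an estimated correlation (adjusted p = 0.0078). Mitosis genes lay above the sum as a list (median 0.24, or 0.21 after quantile normalization; camera adjusted p = 0.000728, and adjusted p = 0.687 with an estimated correlation). Singly, 0 of its 22 genes were called, over all genes, over the list alone or after quantile normalization. The count of 151 fell to 97 without DMSO replicate 3, to 95 without DT replicate 1, to 95 without DT replicate 3, to 93 without E replicate 3 and to 100 without DTE replicate 2. Of the parts, the 69 below the sum were 43 without DMSO replicate 1, DT replicate 2 or E replicate 1, and the 82 above were 49 without DMSO replicate 2 and 54 without DTE replicate 3. It rose to 314 after quantile normalization (174 above and 140 below, of which 82 and 64 were called as deposited).

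The effect of one treatment without and with the other was compared across genes, which are not independent replicates. The DT effect without entinostat (DT against DMSO) and with it (DTE against E) had a Pearson's r of 0.701 and a Spearman's rho of 0.558 over 14580 genes, and the slope of the second on the first was 0.608. That slope was 0.707 in the 465 genes changed at least 2-fold by DT and 0.826 in the 298 changed at least 2-fold in DTE against E. Of the 465 genes changed at least 2-fold by DT, 99.8% moved the same way in DTE against E, against 75.2% of all genes (63.1% after quantile normalization). The entinostat effect without and with dabrafenib and trametinib had an r of 0.685, a rho of 0.534 and a slope of 0.747, and 99.2% of the 355 genes changed at least 2-fold moved the same way, against 67% of all genes (67.9% after quantile normalization). Its slope was 0.832 in these 355 genes and 0.889 in the 436 changed at least 2-fold in DTE against DT. Spread in the effect without the other treatment lowers a slope over all genes. Such slopes therefore do not measure how far one treatment weakened the other.

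**Figure D4:**
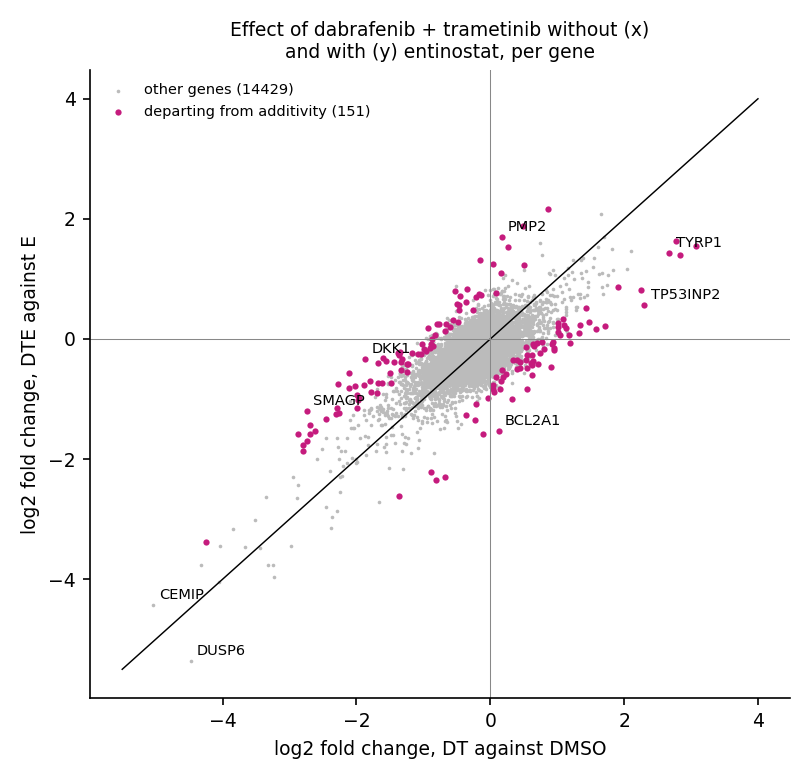
Each point is a gene, with its log2 fold change in DT against DMSO (x) and in DTE against E (y); the line marks equal effects. The 151 genes departing from additivity are coloured, with TYRP1 and TP53INP2 below the line and DKK1 and PMP2 above.

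DT and E calls overlapped. As deposited 179 genes were higher in both against 59 for independent lists, and 271 were lower in both against 124. A further 449 were lower in DT and higher in E, against 440. CD24 was among those raised by both. After quantile normalization 333 were higher in both (121 if independent), 190 lower in both (96.8 if independent) and 222 lower in DT and higher in E (111 if independent). Both comparisons used the same DMSO arrays, so the lists were not independent, and the overlap that shared controls alone would give among changed genes was not measured. In 50 simulations of unchanged groups, the noise of shared controls gave a covariance of 0.0108 between the effects, against 0.0196 observed, and a correlation of 0.502, against 0.144 observed. The simulated correlation follows from the shared controls alone, whereas the observed one also holds the changes of both treatments. Setting these correlations side by side therefore does not show how alike the effects were.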

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

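Of the tests in this part, the permutation of residuals, those of chance differences in brightness, of the shift by level and of the authors' scaling, and the comparison with level-matched random lists as an alternative, were chosen only after the results were seen.

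The test of additivity found genes for which the effect of one treatment differed with the other present: 151 departed. Below the sum were TP53INP2 (-1.74), BCL2A1 (-1.67), TMEM156 (-1.62), PRR9 (-1.54), TYRP1 (-1.24) and OASL (-0.80, a call lost after quantile normalization and without any single array other than E replicate 2 or DTE replicate 2, with values from -0.84 to -0.715). Above it were SMAGP (1.55), CTLA4 (1.55), DKK1 (1.54), PMP2 (1.53), IER3 (1.29), EPHA4 (1.25) and PMAIP1 (1.11). Lists departing in camera were melanocyte differentiation (adjusted p = 3.2e-07), mitosis (0.000728), ERK pathway output (0.0376), homologous recombination (0.0376), dedifferentiated melanoma (0.0376) and ribosome biogenesis (0.0379). After quantile normalization the first 2 were called (1.65e-07 and 0.0104), and the other 4 were not (0.191, 0.0799, 0.0799 and 0.134, in the order given). Single genes called over all genes were 3 of 12 in the melanocyte list, below the sum, and 3 of 17 in ERK output, above it. In mitosis 0 of 22 were called, in homologous recombination 0 of 19, in the dedifferentiated list 0 of 12 and in ribosome biogenesis 0 of 11. Over the list alone 7 ERK output genes lay above and 4 below, and 5 dedifferentiated genes above and 1 below. On the deposited scale ERK output lost its call without DMSO replicate 1 (0.0691), DMSO replicate 2 (0.0582), DT replicate 1 (0.0602), DT replicate 2 (0.0618), E replicate 2 (0.0558), E replicate 3 (0.0819) or DTE replicate 1 (0.121). Homologous recombination lost it without DMSO replicate 2 (0.116), DT replicate 1 (0.0602), DT replicate 3 (0.0568), E replicate 1 (0.0607), E replicate 2 (0.0558) or DTE replicate 3 (0.17). The dedifferentiated list lost it without DMSO replicate 1 (0.12), DMSO replicate 2 (0.0582), DT replicate 1 (0.0602), E replicate 2 (0.0648), E replicate 3 (0.0819) or DTE replicate 1 (0.121). Ribosome biogenesis lost it without DMSO replicate 1 (0.0691), DMSO replicate 2 (0.0735), DT replicate 1 (0.0602), DT replicate 3 (0.0568), E replicate 2 (0.0887), E replicate 3 (0.0819) or DTE replicate 1 (0.121). With an estimated correlation none of the 6 was called (adjusted p = 0.293 for the first and 0.687 for the others). Of 100 random assignments of the 12 arrays to 4 groups of 3, the real one included, 2 gave as many genes, but such assignments mix treated and untreated arrays within groups and so do not decide whether chance gave the departures. The other one gave 480 genes, and the next highest gave 1. That assignment set 5 arrays with entinostat on one side of the contrast against 1 on the other, and 4 arrays with dabrafenib and trametinib against 2, so its count points to a structure of the samples. Which of the 2 treatments gave the count was not tested. With the separate effects of both treatments kept and only the residuals of the additive fit permuted over the arrays, the real order was 1 of 100 to give as many genes (151), and the highest other gave 2. This argues against a chance spread of these arrays as the source of the count.

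The splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split gave 3985 genes in DT against DMSO, 2341 in E against DMSO, 4690 in DTE against DMSO, 2756 in DTE against DT and 3574 in DTE against E. In each of these only 1 split, the real one, gave as many, and the highest other gave 0. Every other split mixes arrays of both groups on each side, so real changes count as spread there. These counts therefore do not decide whether chance gave the calls.

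Probe sets without a gene symbol, used in no comparison above, also differed from DMSO: 2039 of 14648 changed in DT (268 higher, 1771 lower), 1259 in E (998 higher, 261 lower) and 2410 in DTE (819 higher, 1591 lower).

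Most changed genes were lower in the arrays given dabrafenib and trametinib. Chance differences in brightness between single arrays are argued against by the array medians, permuted within arrays alike in entinostat (exact permutation p = 0.01, or 0.035 adjusted over the 7 splits tested). With arrays of both kinds pooled, so that the entinostat shift counts as spread, the adjusted p was 0.0606. A difference shared by all arrays of a group was not tested. Dimming of every gene alike stays open. The ERK output list lay below all 10000 level-matched random lists (percentile 0), but its genes answer the drugs directly and fall with or without a general dimming. The median shift in DT grew with level, from -0.17 in bin 5 of 10 to -0.35 in bin 8, and was -0.37 in bin 9 and -0.36 in bin 10, the brightest. Values of dim probe sets are compressed, so such a dimming could also give smaller shifts in dimmer genes. The trend therefore does not decide. Between the brighter and the dimmer part of the genes above the median level, the shift with the drugs differed by -0.05 (exact permutation p = 0.055) or, by the medians of the levels, by -0.06 (exact permutation p = 0.02, adjusted 0.04), so whether the trend exceeds the spread between arrays also depended on the measure. Dimming cannot be told apart from the authors' scaling or from a wider loss of RNA per cell. After quantile normalization 52.1% of the changed genes in DT against DMSO were higher, which all of these allow, since that normalization removes any general shift. The spike-in that could decide was not analysed here.

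Melanocyte differentiation genes were raised by dabrafenib and trametinib less in the presence of entinostat. The authors' scaling is argued against by the list's departure after quantile normalization (camera adjusted p = 1.65e-07, within a range over the alternatives from 4.83e-09 to 0.293, the last with an estimated correlation, which ends the call on the deposited scale), and the level of the genes alone by their median departure, which lay below all level-matched random lists (percentile 0). Lower MITF expression with entinostat may contribute, as MITF was lower in DTE than in DT (-0.71), but cannot be told apart from other causes. MITF fell about as far with entinostat alone (-0.68) and did not itself depart from additivity (-0.03). A biological interaction of the treatments on this programme stays a hypothesis, found and tested on the same data.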

How the results depend on the processing

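The comparison on protein-coding genes only and quantile normalization for the overlap and the paired effects were chosen after the data were seen. Counts that stayed within 1.5 times their value in every alternative are not repeated here. Centring on the spike-in and its level were not run. The majority of changed genes turned from lower to higher with quantile normalization in DT against DMSO (1247 higher, 1146 lower) and DTE against E (1019 and 851), and from higher to lower with median centring in E against DMSO (1098 and 2372) and DTE against DT (1364 and 2245). Quantile normalization left DTE against DMSO nearly even (2065 and 2064). The cause of a change below was not tested, except that testing every probe set counts more features and treat demands a larger change. Quantile normalization also removes any general shift, and median centring removes the shift of the array medians. Numbers of changed genes were: in DT against DMSO 2393 with quantile normalization and 1290 with treat; in E against DMSO 3577 with every probe set, 3625 with array weights and 794 with treat; in DTE against DMSO 7111 with every probe set and 1900 with treat; in DTE against DT 4215 with every probe set and 1066 with treat; in DTE against E 1985 with median centring, 1870 with quantile normalization and 761 with treat. Departures from additivity numbered 240 with every probe set, 242 with trended and robust moderation, 504 with array weights, 267 with median centring, 314 with quantile normalization and 35 with treat. Leaving out single arrays gave 2659 to 4286 genes for DT, 1730 to 2490 for E, 3737 to 4758 for DTE, 2056 to 2850 for DTE against DT, 2443 to 3682 for DTE against E and 93 to 177 departures. With the replicate number as a block DT called 4228 genes. Whether the replicate numbers pair the arrays was not settled. Deviations from group means correlated at a mean r of 0.0531 over 18 same-numbered pairs, against -0.0265 over 36 other pairs. Only 3 same-numbered pairs lay above 0.1, although 9 of 12 arrays correlated best with their own number. Adjusted p-values of lists that crossed the threshold were, for ERK output in E, 0.0507 (mean of probe sets), 0.0958 (9720 brighter genes), 0.0605 (array weights), 0.0718 (protein-coding) and 0.529 (estimated correlation), with 0.0369 to 0.0932 over single arrays left out. For homologous recombination in DT they were 0.119 (9720 brighter genes), 0.182 (quantile) and 0.572 (estimated correlation), in E 0.529 (estimated correlation) and in DTE 0.0689 (9720 brighter genes) and 0.515 (estimated correlation). For melanocyte differentiation they were 0.0413 (only the groups compared) and 0.049 (replicate block) in E, with 0.0396 to 0.0965 over single arrays, 0.0152 (quantile) in DTE, with 0.0464 to 0.115 over single arrays, and 0.293 (estimated correlation) for the departure from additivity. The ERK output list in DT stayed between 8.58e-38 and 1.24e-29 over single arrays. Pearson's r of the DT effect without and with entinostat was 0.722 in genes changed in either, 0.735 in the 9720 brighter genes and 0.674 with quantile normalization, and of the entinostat effect 0.749 and 0.732 in the first pair of settings. Genes higher in both DT and E numbered 10 at 2-fold and 333 with quantile normalization, and those lower in both 3 at 2-fold. Over all lists and comparisons the estimated correlation ended 48 list results and quantile normalization 15, while 4 passed only after it. Only ERK output, cholesterol synthesis and melanocyte differentiation kept any call as deposited with the estimated correlation. ERK output and cholesterol synthesis kept it in DT, DTE and DTE against E, and melanocyte differentiation in DT alone. In the simulated data, where 200 genes changed, 46.4% of 1.5-fold changes were recovered. The comparisons between groups called more genes, which loosens the adjusted threshold, so this share does not set their limit of detection. Dim genes near an intensity of 2 can show little fall.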

Other observations

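The separate count of dim genes away from the floor was chosen only after the result was seen.

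Interferon-stimulated genes were not called as a list in any comparison (adjusted p = 0.631 in DT, 0.189 in E, 0.348 in DTE), but single members moved far. IFI44L rose by 1.93 and IFIT1 by 1.25 in DTE, and OASL rose by 1.13 in E, while RIGI, a sensor of viral RNA, fell by 1.14 in DT. In DT 3 of 16 rose and 3 fell (3 and 1 after quantile normalization), in E 6 rose and 2 fell (5 and 2), and in DTE 3 rose and 3 fell (6 and 2). Histone deacetylase genes, the family that entinostat inhibits in part, rose in E in 4 of 11 cases and fell in 0 (5 rose over the list alone, camera adjusted p = 0.128), among them HDAC5, by 0.77. HDAC4 had a second, dimmer probe set that these counts leave out. In E it stood at -1.24, against -0.16 for the one used, and in DT at 0.36, against -0.81. The call of HDAC4 in DT was lost with the mean of its probe sets (-0.23). Of the entinostat targets, HDAC2 rose by 0.56 in E (adjusted p = 0.016; 0.41 after quantile normalization), a call lost without DMSO replicate 3 (0.45) or E replicate 2 (0.46), HDAC1 stood at 0.31 in E (adjusted p = 0.098), and HDAC1 and HDAC3 stood at -0.36 and -0.39 in DT as deposited and at 0.01 and -0.02 after quantile normalization. In DT 1 of the deacetylase genes rose and 4 fell as deposited, and 3 rose and 1 fell after quantile normalization (median -0.19 and 0.09; adjusted p = 0.717). The 4 MHC class I presentation genes measured included 2 that fell in DT, ERAP2 by 0.89 (adjusted p = 0.158 for the list). The 2 cancer-testis antigens measured did not pass in DT (adjusted p = 0.571 for the list).

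In lysosome and autophagy 2 of 13 genes rose and 1 fell in DT as deposited, and 8 rose after quantile normalization (median 0.16 and 0.52; camera adjusted p = 0.00921 and 0.000184, and adjusted p = 0.469 with an estimated correlation). In DTE against DT 1 of 13 rose and 3 fell, HEXA, a lysosomal enzyme, by 0.65 (camera adjusted p = 0.0228, and adjusted p = 0.592 with an estimated correlation). Of 7 glycolysis genes 5 fell in DT, HK2 by 1.00 (median -0.56, or -0.20 with 1 falling after quantile normalization; camera adjusted p = 0.0334, 0.263 after quantile normalization, and adjusted p = 0.523 with an estimated correlation). Among protein-coding genes 31.4% were changed in DT as deposited, against 10.8% of long non-coding RNAs and 9.23% of microRNA genes, whose mean log2 levels of 3.33 and 2.93 lay below the 5.21 of protein-coding genes. After quantile normalization 1168 of 11718 protein-coding genes were higher and 1053 lower. The counts there were 49 and 58 of 1361 long non-coding RNAs and 15 and 23 of 1018 microRNA genes.

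Most genes moved at least 2-fold by entinostat rose, 337 against 18 as deposited, 204 against 27 after quantile normalization and 176 against 50 after median centring, and derepression of genes near the background was one hypothesis for them. In the DT arrays, which the E against DMSO values do not use, the raised genes had a median level of 4.43, against 4.48 for all genes, a value within that of random gene sets of the same size (percentile 39.6). Derepression may still hold for the dim part, 51.9% of the raised genes, so the test leaves it open. A larger spread of dim genes, which would lower as many genes as it raises, is argued against as the source only as far as falls of dim genes can be seen. Below the median level 175 rose and 2 fell, so 98.9% rose (exact 95% interval 96 to 99.9). After quantile normalization 97 rose and 4 fell there. The exact intervals treat genes as independent, and the counts of dim genes were not made after median centring. As genes at the floor cannot fall, genes between a level of 2.91 and the median were counted apart, and there 152 rose and 2 fell (98.7%, exact 95% interval 95.4 to 99.8). A 2-fold fall from the lower part of this range still ends below 2.91, where levels were not shown to lie above background. Falls may therefore be missed there too, and the count does not fully remove the effect of the floor.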
